A study of Mus musculus with 6 samples.

How the data were processed

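ATAC-seq libraries of sorted urothelial cells were used from 3 Stag2 WT and 3 Stag2 KO samples, collected 1 week after TMX induction, with 50000 cells per condition, per the labels. Each sample had a list of peaks in narrowPeak format, called on that library and not on pooled libraries. The file names read as trimmed reads with duplicates and mitochondrial reads removed, Tn5 insertion positions, a p threshold of 0.01, a limit on the number of peaks and a blacklist filter. The genome build was mm10 and DiffBind was among the tools, per the submitters' processing notes, and no DiffBind output was used here. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists give for each peak a fold over the local background (a ratio), a −log10 p and a −log10 q, all by the authors' peak caller, a display score that was not used in any test, and the position of the summit within the interval, also deposited by the authors. The fold, p-value and q-value of a peak depend on depth, so they were used only to describe, rank or filter peaks within a list. The list of KO replicate 1 reached the limit on peaks and started at a −log10 p of 3.00, while the others started at 2.00.

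Several summits can share an interval, so each list was reduced to distinct intervals with their best p, which removed 13.1% to 19.9% of the peaks. Lists of different lengths cannot be compared by rank. Each list was therefore shortened to its 50000 intervals of best p (ties by fold, then position), and these were merged to regions where they overlapped by at least 1 bp. A KO-only region had a peak in the 3 KO lists and in none of the WT lists, and a WT-only region the reverse. For tests of rank, the best 100000 intervals of each library were used, and a region without an interval received rank 100001. The −log2 ranks of regions with a peak in at least 3 libraries were compared with limma 3.58.1 in R 4.3.3, with moderated variances, a trend and Benjamini-Hochberg adjustment at 0.05. Overlap was measured by the Jaccard index in base pairs. This and the other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6. The merging of intervals was checked against bedtools 2.31.1 on simulated intervals. Figures were drawn with matplotlib 3.10.9.

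Depth was read from the lists. If the fold is (k + 1) / (λ + 1) and p the Poisson tail beyond k for a background λ, whole coverages k gave both values within 0.002 in −log10 p for 100% of 4000 peaks sampled per library. The smallest λ is given as the background coverage of a library. It ranged from 5.89 to 7.98, and this depth limits which weak peaks were listed. The depth was used only as a description.

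The gene annotation was a table of GRCm38.p6 gene spans, whose coordinates are those of mm10. It gives neither strand nor exons, and no genome sequence was used here. Promoters were planned, and in their place windows of 500 bp on either side of both ends of each protein-coding gene were examined. For each gene, the end with the better mean −log2 rank over the 6 libraries was used, without regard to genotype. Neighbouring genes can share a window, and 1 of the 2 ends is the 3' end. Regions were classed as gene end, gene body or intergenic, without exons or UTRs, and named by the nearest protein-coding gene end within 50 kb. Motifs were not analysed here.

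Before the data were examined, 14 gene lists were fixed: DREAM targets of G1/S and of G2/M, DREAM and MMB subunits, cohesin and CTCF, CDK inhibitors and quiescence, urothelial luminal and basal genes, immediate early and AP-1 genes, interferon and inflammation, markers of fibroblasts, smooth muscle, endothelium and immune cells, and housekeeping controls. Lists were tested with camera (preset correlation 0.01, and estimated) and fry in limma. Named genes were fixed as Stag2 and Stag1, the list members with the smallest p in each direction (2 per direction for the DREAM target, luminal, basal and AP-1 lists), the 5 regions per direction with the smallest p, and the 5 KO-only and 5 WT-only regions with the best mean rank and no peak in the whole lists of the other genotype. Single values were compared with two-sided exact permutation tests, whose smallest p is 0.1 for 3 against 3, and shares of regions with Fisher's exact test.

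The alternatives fixed in advance were other list lengths (25000, 100000, whole lists), a −log10 q of at least 2, ranking by fold, 501 bp windows, an overlap of 50%, linear ranks, other peak requirements, windows of 1000 bp at gene ends, a distance of 10 kb, a block on the replicate number and leaving out each library. Autosomes only, the gene-end share as a covariate, settings for the regions absent from whole lists and a shorter rank list for the gene lists were added after seeing the data. The rank test was tested on simulated lists made from the intervals of WT replicate 2 with 200 changed regions in a comparison of KO with WT. At a coefficient of variation of 0.1 between replicates, with 51475 regions tested, it recovered 88% of regions changed 2-fold and 96% changed 4-fold, with 4 false calls. At a coefficient of variation of 0.2, with 52417 tested, it recovered 27% and 90%, with 1 false call. Without changed regions it made 0 calls at either coefficient. The simulated noise was drawn independently for each region and library. These counts therefore do not cover false calls from differences that several libraries share.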

Results

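Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in urothelial cells of mice with (WT) or without (KO) a working Stag2 gene. Stag2 encodes a subunit of cohesin, the ring complex that holds sister chromatids together and extrudes chromatin loops. The cells came from peeled urothelium, the lining of the bladder, and were sorted as GFP-positive, DAPI-negative cells 1 week after TMX was given to induce the deletion. There were 3 WT and 3 KO libraries, all in batch 1 per the labels, and each library had its own peak list. The lists held between 181987 and 299636 peaks, or between 149153 and 260462 distinct intervals. The background coverage implied by the peak caller's fold and p was 7.59, 6.37 and 6.90 in the WT libraries and 7.98, 5.89 and 6.88 in the KO libraries, and did not differ between genotypes (exact permutation test, two-sided p = 0.9, n = 3 per group). With 3 libraries against 3, the smallest p this test allows is 0.1. The libraries are called biological replicates in the labels, which do not say how many animals each came from, so p-values measure the spread between these 6 libraries.

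The lower end of the Stag2 span (chromosome X, 42149297 to 42277186, build mm10) was open in all 6 libraries. The interval there held rank 20169, 11913 and 17473 in the WT lists, where rank 1 has the best p, and rank 7120, 4989 and 14688 in the KO lists. The log2 rank gain in KO was 1.00 ± 0.42 (SE, n = 3 per group), which did not pass the test over all gene ends (limma, adjusted p = 0.257). Without each library the gain was 0.66 to 1.44, and it passed only without KO replicate 3. In that fit 4512 of 13391 gene ends passed as higher and 904 as lower. The gain also passed with a block on the replicate number, and it fell to 0.05 with the gene-end share as a covariate. A peak at a gene end need not report on exons deleted elsewhere in the gene, so it does not check the genotype labels. Stag1, the gene of the paralogous cohesin subunit, had no interval within 500 bp of either end of its annotated span (chromosome 9, 100597709 to 100958544) among the best 100000 intervals of any library, and was not tested.

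The first question was how far the accessible regions were shared between genotypes. The 50000 best intervals of each library merged into 67594 regions, and 34315 of them (50.8%) had a peak in all 6 libraries. In base pairs, the mean Jaccard index was 0.707 within genotypes and 0.656 between them. The difference of 0.0517 was smaller than that of another split of the libraries, at 0.0809 (exact permutation test over 10 splits, one-sided p = 0.2). Single pairs did not all follow the genotype. The highest index, 0.775, was between KO replicates 1 and 2. KO replicate 3 had 0.681, 0.754 and 0.749 with the WT libraries, and 0.659 and 0.662 with KO replicates 1 and 2. WT replicate 2 had 0.676 and 0.737 with WT replicates 1 and 3, and 0.695, 0.714 and 0.754 with the KO libraries. The median width of these intervals was 492 ± 19.5 bp in WT and 446 ± 15.6 bp in KO (SD, n = 3 each, exact permutation test, p = 0.1).

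Some regions were open in every library of 1 genotype and in none of the other. An interval inside Drc1, a gene of motile cilia (chromosome 5, 30287995 to 30288594), held rank 5090, 6547 and 2413 in the KO libraries, and no WT list had a peak there at any rank. Inside Lrch1 (chromosome 14, 74828062 to 74828598), the KO ranks were 14799, 19339 and 18683, and inside Prkd2, which encodes a protein kinase D (chromosome 7, 16863799 to 16864258), they were 29541, 33204 and 13801, again with no peak in any WT list. In the other direction, an interval inside Abcc4, which encodes a membrane transporter (chromosome 14, 118642861 to 118643458), held rank 2624, 5279 and 4614 in the WT libraries and was missing from the 3 KO lists. An intergenic interval on chromosome 5 (18502782 to 18503315) held rank 6598, 4093 and 4656 in WT and was likewise missing from the KO lists. The remaining all-or-none regions with the best mean rank were intergenic. The KO-only ones lay on chromosome 9 (9376144 to 9376510) and on chromosome 14 (72392893 to 72393580), the latter 38080 bp from Gm9195. The WT-only ones lay on chromosome 9 (17508681 to 17509096) and on chromosome 14 (86197516 to 86198256 and 86537612 to 86538155).

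Among the 50000 best intervals per library, 658 regions were KO-only and 538 were WT-only. When absence was judged in the whole lists of the other genotype, 15 KO-only and 9 WT-only regions were left. KO-only regions overlapped a gene end in 8.81% of cases, against 18.6% of the other regions (Fisher's exact test across regions, p = 4.35e-12), and WT-only regions in 4.28% against 18.6% (p = 9.28e-23). These p-values take regions as units and do not measure the spread between libraries. The regions were not matched on peak strength or width (median 420 and 434 bp, against 523 bp). Gene ends made up 20.2% to 23.5% of the 50000 best intervals of a library, and 13.8% to 14.9% of the 100000 best. The lower shares can therefore come from weaker peaks. Leaving out a library loosens the rule, so by construction the counts of KO-only and WT-only regions can only stay or rise. How far they rose differed between libraries. Without KO replicate 3 they were 2858 KO-only and 3245 WT-only, without WT replicate 2 they were 1862 and 1928, and without WT replicate 1 the WT-only count was 893. The counts against whole lists rose to 36 KO-only without KO replicate 2, to 23 KO-only without WT replicate 2, and to 21, 16 and 14 WT-only without KO replicate 3, WT replicate 3 and WT replicate 2.

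The position of each region in the lists was then compared between genotypes, as a log2 rank gain in which +1 means a rank that is a factor of 2 better in KO. Of 51121 regions with a peak in at least 3 libraries, 32 ranked higher in KO and 25 ranked lower (limma, adjusted p below 0.05). With a rank list of 50000 intervals, or with linear ranks, these counts were 3 and 3. Besides Drc1 (gain 4.53 ± 0.35, SE, n = 3 per group, adjusted p = 0.000627), the regions with the smallest p among those higher in KO were an intergenic interval on chromosome 13 (40605901 to 40606605), an interval inside Ptprm, a receptor tyrosine phosphatase gene (chromosome 17, 66738282 to 66739036), and an intergenic interval 11027 bp from Slc25a30, a mitochondrial carrier gene (chromosome 14, 75798064 to 75798520). The gains were 3.64 ± 0.22 on chromosome 13, 2.84 ± 0.21 in Ptprm, 3.39 ± 0.29 near Slc25a30 and 2.52 ± 0.22 in Lrch1, with limma adjusted p between 0.000170 and 0.00170. Lower in KO were the Abcc4 interval (gain -4.64 ± 0.30, limma adjusted p = 0.000195), the chromosome 5 interval (-4.32 ± 0.26), the chromosome 9 interval (-3.40 ± 0.23), an intergenic interval on chromosome 14 (73449136 to 73449531, -2.65 ± 0.21) and an interval inside Eif2ak4, the gene of the amino acid sensor kinase GCN2 (chromosome 2, 118402205 to 118402885, -2.75 ± 0.26). With a rank list of 50000 intervals, 5 of these 10 regions lost their call (limma): those in Ptprm and near Slc25a30 (adjusted p = 0.0620), in Lrch1 (0.105), at 73449136 on chromosome 14 (0.0796) and in Eif2ak4 (0.109). The Eif2ak4 region also lost it without WT replicate 1 (0.0551). Of the other named all-or-none regions, those in Prkd2 (limma, adjusted p = 0.0516) and at 86537612 on chromosome 14 (0.0577) were not called. Those at 72392893 and 86197516 on chromosome 14 (0.0247 and 0.0320) lost their calls with a rank list of 50000 (0.252 each). They also both lost them without WT replicate 1, WT replicate 3 or KO replicate 1. In addition, the region at 72392893 lost its call without WT replicate 2 (limma, adjusted p = 0.0505). The region at 86197516 lost its call without KO replicate 2 (0.101) and with the gene-end share as a covariate (0.102). The chromosome 9 region at 9376144 (0.00225) lost its call with that rank list (0.118) and without WT replicate 1 (0.0515). A library without an interval was given rank 100001, so gains against such libraries depend on the list length. Where all 3 libraries of a genotype held that rank, they added no spread. The SE and adjusted p then rested on the spread in the other genotype and on limma's moderated variance. That was so for 27 of the 57 called regions.

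Of the 57 called regions, 31 were intergenic, 21 lay in gene bodies and 5 overlapped a gene end (8.77%, against 21.3% of the other tested regions, Fisher's exact test across regions, p = 0.0220). These regions were not matched on peak strength either. With the called regions included, 4788 regions higher and 5556 lower had an unadjusted p below 0.05. This balance turned with the gene-end share as a covariate (1778 higher and 1159 lower) and with ranking by fold (4296 and 3464). The number of calls depended on single libraries: without KO replicate 3 it was 6461 higher and 8586 lower, and without WT replicate 1, WT replicate 3, KO replicate 1 and KO replicate 2 it was 5 and 4, 14 and 5, 13 and 8, and 16 and 10. Among the 59414 regions with a peak in all 6 rank lists, 2 were higher and 2 lower. That set leaves out regions without a peak in the rank lists of 1 genotype, to which 27 of the 57 called regions belong.

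**Figure D1:**
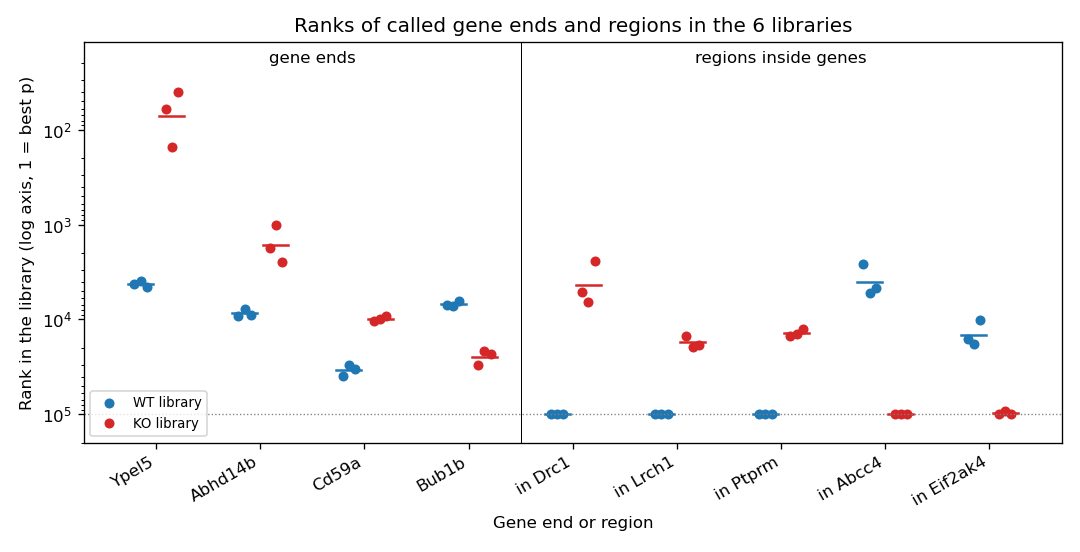
Rank of the peak (log axis, rank 1 at the top has the best p) at 4 called gene ends and 5 called regions inside genes, with 1 point per library (3 WT in blue, 3 KO in red), bars at the geometric mean and a dotted line at rank 100001, which stands for no interval. At Ypel5 the WT libraries sit between 3963 and 4510 and the KO libraries between 40 and 152.

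Gene ends were tested next, since the annotation used gives the span of a gene without its strand. The end of Ypel5, a member of the yippee-like family (chromosome 17, 72836628 to 72850444), held rank 4200, 3963 and 4510 in WT and rank 60, 152 and 40 in KO, a gain of 5.88 ± 0.54 (SE, n = 3 per group, limma adjusted p = 0.000424). Abhd14b rose by 2.39 ± 0.40, Ceacam19 by 2.12 ± 0.34 and Cd59a, which encodes a complement inhibitor, by 1.81 ± 0.29 (limma adjusted p between 0.0470 and 0.0476). Bub1b, which encodes the spindle checkpoint kinase BubR1 (chromosome 2, 118598202 to 118641592), ranked lower in KO, at 30313, 21508 and 23284 against 7008, 7205 and 6465 in WT, a gain of -1.85 ± 0.31 (limma adjusted p = 0.0476). Bub1b kept its direction in every alternative run, with gains of -2.16 to -1.70, and missed the threshold when ranks came from fold (adjusted p = 0.306), with a rank list of 50000 intervals (0.0648), with the gene-end share as a covariate (0.0795) and without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 2 (0.0979 to 0.578). Bub1b came from a rule fixed in advance, which took the G2/M targets with the smallest p in each direction. The other genes were named after their values were seen.

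In all, 6 of 13391 gene ends ranked higher in KO and 10 lower (limma, adjusted p below 0.05), with 1890 and 626 at an unadjusted p below 0.05. With the gene-end share as a covariate the unadjusted counts were 219 higher and 421 lower, so their balance turned. With windows of 1000 bp around the gene ends in place of 500 bp, 7 of the 16 were called again in the same direction, 4 higher and 3 lower. The other 9, among them Wdr74, Rpl4 and Gart, had a gain below 1 in size there. All 9 kept the same end, and the wider window took in better-ranked intervals in at least 3 libraries each. At some of the 16, such as Wdr74, all 3 KO libraries held rank 100001, so KO added no spread to the SE. Without KO replicate 3 the counts were 4512 higher and 904 lower, without WT replicate 2 they were 15 and 50, and without WT replicate 1, WT replicate 3, KO replicate 1 and KO replicate 2 they were 1 and 7, 1 and 5, 2 and 6, and 3 and 10. The median gain of all tested gene ends was 0.32, and the gene lists below are set against it.

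The series title names DREAM, the complex that represses cell cycle genes in resting cells, so DREAM targets were examined at gene ends. Most were already open in WT: of 40 targets of the G1/S phase, 33 to 34 had a peak among the 50000 best intervals of each library, and of 40 targets of the G2/M phase, 37 to 40 did. The G2/M targets moved down relative to the other gene ends, with a median gain of -0.12 over 39 tested members against 0.32 for all (camera, adjusted p = 0.00248). The call was lost with an estimated correlation between genes (adjusted p = 0.587). It was also lost with the gene-end share as a covariate (0.352), where the distance from all gene ends went from -0.44 to -0.08. Interferon genes and fibroblast markers had medians about as low (-0.07 and -0.09) without passing. Of the 39 members, 17 had a positive and 22 a negative gain. Bub1b alone was called, over all genes and when adjusted over the list alone. Values that did not pass were a gain of -1.49 ± 0.46 for Top2a, the topoisomerase of mitotic chromosomes, 0.95 ± 0.34 for Prc1, a spindle midzone protein, and 0.93 ± 0.37 for the checkpoint kinase gene Bub1. The G1/S targets had a median gain of 0.10 over 37 members (camera, adjusted p = 0.171) and no called member, over all genes or adjusted over the list alone. Among them, uncalled gains were 0.93 ± 0.31 for Mcm2 and -2.08 ± 0.73 for Mcm3, subunits of the replicative helicase, 0.86 ± 0.38 for Brca2 and -3.04 ± 1.24 for Brca1, both of DNA repair. The Brca1 window is shared with a neighbouring gene, and its KO ranks were 50306, 2144 and 435. The Brca1 gain was -1.14 without KO replicate 1, -1.37 with windows of 1000 bp, -0.97 by fold and -0.81 with the gene-end share as a covariate. Without KO replicate 3 it was -4.57 and was called (limma, adjusted p = 0.00188). That call was not particular to Brca1, since 4512 of 13391 gene ends were called higher there and 904 lower. Called members there numbered 6 higher and 4 lower for the G1/S targets, and 5 and 9 for the G2/M targets. Mcm2, Mcm3, Brca2, Top2a, Prc1 and Bub1 were among them.

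None of the other 12 lists passed camera at an adjusted p of 0.05. The 14 genes of DREAM and MMB subunits had a median gain of 0.58 (adjusted p = 0.172), with Dyrk1a, a kinase that promotes DREAM assembly, at 0.92 ± 0.31 and Lin52 at -0.40 ± 0.42, uncalled. Cohesin and CTCF genes had a median of 0.38 (0.736), with Smc1a at -0.96 ± 0.36. CDK inhibitor and quiescence genes had a median of 0.24 (0.736), with Cdk4 at 0.88 ± 0.39 and Btg2 at -1.29 ± 0.35. Luminal urothelial genes had a median of 0.40 (0.430), with the uroplakin gene Upk1b at 1.29 ± 0.35, Epcam at 0.89 ± 0.31, Ehf at -0.77 ± 0.40 and Upk1a at -0.34 ± 0.32, and basal genes had a median of 0.40 (0.443), with Itgb4 at 1.12 ± 0.41, Dst at 0.86 ± 0.33, Krt14 at -0.48 ± 0.21 and Cd44 at -0.40 ± 0.32. Immediate early and AP-1 genes had a median of 0.26 (0.865), with Ier2 at 1.02 ± 0.39, Atf3 at 0.83 ± 0.34, Jun at -0.64 ± 0.36 and Fosl2 at -0.61 ± 0.45. In these lists no member was called, over all genes or adjusted over the list alone. Without KO replicate 3, where 4512 of 13391 gene ends were called higher and 904 lower, members of each of these lists were called. They numbered 10 higher and 1 lower for luminal genes, 8 and 1 for basal genes and 6 and 2 for CDK inhibitor and quiescence genes. Cohesin and CTCF genes had 5 and 1. DREAM and MMB subunits had 6 and 0, as did immediate early and AP-1 genes. The gains of Lin52, Btg2, Ier2 and Jun turned sign when ranks came from fold, those of Krt14 and Ier2 with windows of 1000 bp, and those of Ehf, Upk1a and Fosl2 with the covariate.

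Interferon and inflammation genes had a median gain of -0.07 (camera, adjusted p = 0.0530), with B2m at -1.58 ± 0.51 and Cxcl1 at 0.67 ± 0.37 (negative with the covariate), with no called member over all genes or adjusted over the list alone. The list passed without WT replicate 3 (adjusted p = 0.0122) and without KO replicate 1 (0.0301), and with an estimated correlation both calls were lost (0.486 and 0.752). Markers of other cell types had medians of -0.09 for fibroblasts (0.171), 0.06 for smooth muscle (0.430), 0.51 for endothelium (0.171) and 0.07 for immune cells (0.430). Among the 50000 best intervals of each library, 2 to 4 of 16 fibroblast genes, 3 to 5 of 10 smooth muscle genes and 2 to 4 of 20 immune genes had a peak. Of 13 endothelial genes, 0, 2 and 0 did in WT and 2 did in each KO library. Their members with the smallest p were Fbln1 (0.58 ± 0.28), Col1a1 (-0.89 ± 0.25), Des (0.64 ± 0.30, negative with the covariate), Lmod1 (-0.45 ± 0.32), Flt1 (0.89 ± 0.32), Coro1a (0.59 ± 0.26) and Csf1r (-0.60 ± 0.27). No marker was called over all genes, and 2 endothelial genes were higher when adjusted over the list alone. Housekeeping genes had a median of 0.25 (0.430), with Eef1a1 at 0.60 ± 0.32 and Rps18 at -1.16 ± 0.38, and no called member either way. Without KO replicate 3, members of each list in this paragraph were called as well, among them 4 housekeeping genes higher and 2 lower.

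**Figure D2:**
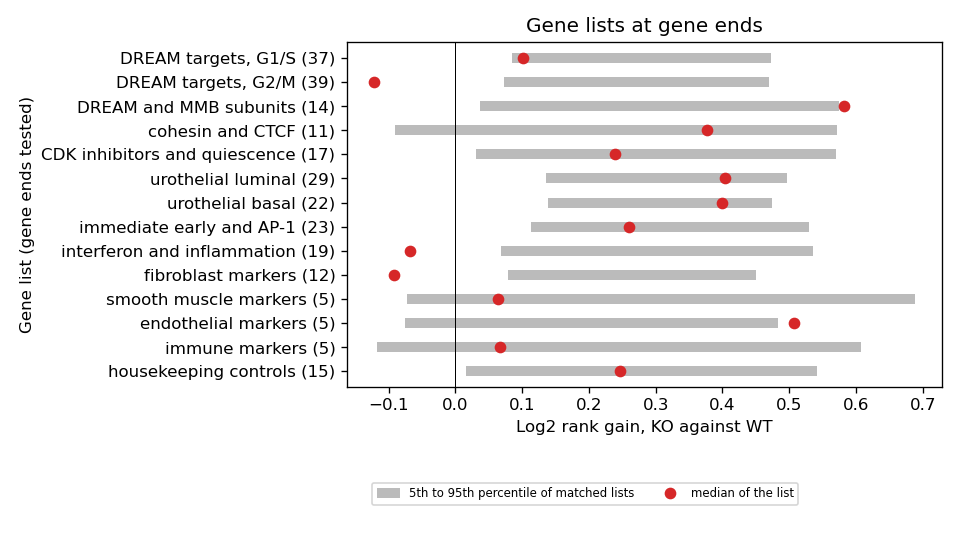
Median log2 rank gain of each gene list at gene ends (red points, number of tested genes in parentheses) and the range from the 5th to the 95th percentile of random lists of the same size matched on mean rank (grey bars). The G2/M targets, at -0.12, and 2 other lists lie below their bars, and 2 lists lie above them.

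Genes of the lists were also looked for near the all-or-none regions, by the nearest gene within 50 kb. KO-only regions lay near 1 G1/S target (E2f2), the CDK inhibitor locus Cdkn2a and the cyclin-dependent kinase gene Cdk6, the AP-1 and immediate early genes Egr2, Fosb and Junb, the basal regulator Trp63, and B2m, Fbln1, Flt1 and Ywhaz of other lists. WT-only regions lay near Trp63, Fosb, Klf4 and the immune genes Cd52 and Csf1r. In none of the 14 lists did the share pass against that among the other regions near genes (Fisher's exact test across regions, smallest adjusted p = 0.985 for KO-only and 0.185 for WT-only). The 0.185 belonged to the immune genes, at 2 of 26 regions (unadjusted p = 0.0132), the only list below 0.05 before adjustment. A region 1816 bp from Cd52 (chromosome 4, 134096889 to 134097632) was called lower in KO (gain -1.86 ± 0.22, limma adjusted p = 0.0126), and a region 9213 bp from B2m (chromosome 2, 122137977 to 122138474) higher (2.01 ± 0.22, adjusted p = 0.00641); both were named after their values were seen.

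Intervals at gene ends made up 20.7 ± 0.58% of the 50000 best in WT and 22.4 ± 1.40% in KO (SD, n = 3 each, exact permutation test, p = 0.2). Intervals on chromosome X made up 1.52 ± 0.028% in WT and 1.59 ± 0.0083% in KO (exact permutation test, p = 0.1, adjusted p = 0.42 over the chromosomes), and with 100000 intervals per library the order was the reverse, at 1.83% and 1.77%.

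**Figure D3:**
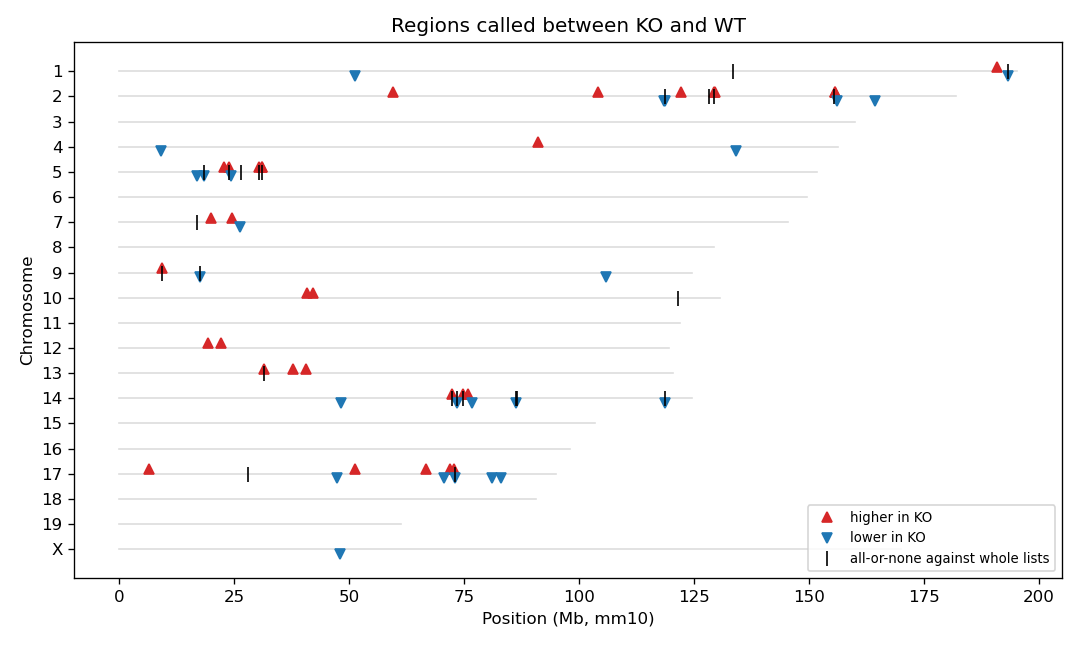
Positions in Mb (build mm10) of the 57 regions called between genotypes, as triangles pointing up for the 32 higher in KO and down for the 25 lower, with the 24 regions absent from the whole lists of the other genotype as vertical ticks; grey lines run to the last region of each chromosome. Chromosomes 2, 5, 14 and 17 hold 37 of the 57 called regions.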

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

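The autosomes, the covariate, the settings of regions absent from whole lists and the shorter rank list for gene lists were chosen after seeing the data. Depth limits which weak peaks were listed, and whole lists differ in length and threshold. The cause of a change was not tested unless stated.

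KO-only and WT-only regions numbered 349 and 286 with 25000 intervals per library, 1234 and 1164 with 100000, 1688 and 3177 in whole lists, 1467 and 2995 at a −log10 q of at least 2, and 15 and 9 with absence judged in whole lists, by construction of longer or shorter lists. Leaving out each library, which can only keep or raise these counts, gave 754 to 2858 and 660 to 3245. An overlap of 50% moved nothing by construction, since a merged region contains its peaks. Regions absent from whole lists numbered 3 and 5 with 25000 intervals and 114 and 112 with 100000, and 15 to 36 and 10 to 21 without each library. The within-genotype excess of the Jaccard index stayed positive in every setting (0.0244 to 0.112 without each library).

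Regions higher and lower in KO numbered 2 and 2 with a peak in all 6 rank lists, 58 and 53 with a peak in at least 1 library, 3 and 3 with a rank list of 50000, 3 and 3 with linear ranks, and 5 to 6461 and 4 to 8586 without each library. Of the 57 calls, 35 were shared with the covariate and 35 with ranking by fold, in the same direction. Gene ends numbered 1 and 5 with a rank list of 50000, 3 higher when ranked by fold, 2 higher with the covariate, and 1 to 4512 and 5 to 904 without each library. Whether the replicate numbers pair the libraries was not settled. Deviations of same-numbered libraries from their genotype means correlated at -0.26, 0.50 and 0.56 over regions, and not every library correlated best with its own number. Such deviations sum to 0 over the 3 libraries of a genotype, so their correlations depend on each other and cannot exclude pairing. By the library names in the labels, the second pair is numbered 3 in WT and 2 in KO. With a replicate block the counts were 1411 higher and 2299 lower for regions and 1393 and 452 for gene ends.

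The G2/M list kept its direction throughout, with a median distance from all gene ends of -0.44 and an estimated-correlation adjusted p of 0.587, and of -0.0798 with the covariate (adjusted p = 0.352), and of -0.54 to -0.27 without each library. The G1/S list was at -0.0134 with the covariate, where camera's direction turned, and at -0.45 to -0.08 without each library. Lists past camera numbered 0 with an estimated correlation and 1 to 2 without each library. With fry, which tests a list against no change and not against the other gene ends, 0 lists passed. With the covariate the list past camera was the luminal one (adjusted p = 0.0358, and 0.696 with an estimated correlation, so that call was lost too), not G2/M. The gene-end share was higher in KO in every setting (1.11 to 2.47 percentage points without each library). The chromosome X share was lower in KO, by -0.0533 percentage points, with 100000 intervals. Lists near regions gave 0 calls at 50 and 10 kb. The smallest adjusted p values at 10 kb belonged to immune genes (Fisher's exact test). They were 0.0537 near regions called lower in KO and 0.0578 near WT-only regions.

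Of the named uncalled gene ends, 10 turned sign, 11 times in all, in 3 settings: ranking by fold, windows of 1000 bp and the covariate. Motifs were not run.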

Other observations

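The counts over other splits of the libraries were planned, although what they would show was written down only afterwards; the other tests and the named genes in this part were chosen after the results were seen. Besides the regions already named, the gene ends called in both window sizes held Ypel5, Abhd14b, Cd59a and Ceacam19 higher in KO and Bub1b, Gm28710 and Gm13286 lower. Called regions without a gene end lay inside Foxo3, a transcription factor gene of resting cells (chromosome 10, 42222104 to 42222700, gain 1.59 ± 0.23, limma adjusted p = 0.0383), inside Clip4 (chromosome 17, 71827073 to 71827431, 1.87 ± 0.26, adjusted p = 0.0330), and 24414 bp from Apln on chromosome X (48059267 to 48059755, -1.62 ± 0.24, adjusted p = 0.0396).

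The libraries differed along an axis that followed the genotype only in part. The first principal component of the region ranks held 71.3% of the variance, with scores of 0.47, -0.02 and 0.43 in WT and -0.51, -0.55 and 0.18 in KO. Over the 6 libraries it followed the share of intervals at gene ends (Pearson r = -0.970, exact permutation p = 0.00278, adjusted p = 0.0111; Spearman rho = -0.943, p = 0.0167, adjusted p = 0.0667; r = -0.899 without the 2 libraries farthest from the median share), and it did not pass against background coverage (r = 0.199, exact permutation p = 0.701) among 4 measures tested. The share is counted on the same ranked lists as the component, so a general shift of gene ends moves both. The relation with the share is therefore partly built in, and it cannot show what sets the axis. The 2 libraries farthest from the median coverage were KO replicate 1, with the highest (7.98), and KO replicate 2, with the lowest (5.89). Their scores were nearly equal (-0.51 and -0.55). Without these 2 libraries the r with coverage was 0.861, but leaving out both extremes of coverage means it cannot decide whether depth plays a part.

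With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 57 regions, and 2 splits of the 10 called as many, the highest other being 11568, from WT replicates 1 and 3 with KO replicate 3 against the rest. For gene ends the real split called 16, the highest other 3636, and 2 splits called as many. For KO-only and WT-only regions together the real split gave 1196, the highest other 2659, and 2 splits gave as many. The same split was the highest in each case, which points to a structure of the samples. The regions absent from whole lists numbered 24 in the real split and 0 in each of the other 9.

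Called regions lay close together. Of the 57, 28 had another within 2 Mb, against a median of 7 and a highest value of 22 in 10000 random draws of tested regions (one-sided permutation p = 0.0001, the smallest the draws can give), which argues against placement by chance. Chromosomes 2, 5, 14 and 17 held 37 of them. Stretches of chromosome that change in 1 direction were argued against as the whole cause, since 55.6% of 18 neighbouring pairs shared their direction (exact binomial 95% interval 30.8% to 78.5%), with a shuffled median of 50%. A strain haplotype that differs between the WT and KO animals may also give clustered regions in both directions, and it cannot be told apart from the genotype because the labels used here give no strain; the bound of 78.5% only leaves it open. Bub1b had 2 called regions within 2 Mb of its end and Ypel5 had 3, the regions at these genes included.

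The lower position of G2/M DREAM targets relative to other gene ends was weighed likewise. Less room to move for strong peaks was argued against, since the list's median lay at percentile 0.13 of 10000 random lists matched on mean rank, although of the 14 lists 3 lay below the 5th percentile (G2/M, interferon and fibroblast genes) and 2 above the 95th (DREAM and MMB subunits and endothelial genes). Bub1b alone was argued against, since without it the camera p was 0.000913 (0.0549 with an estimated correlation). Differences between libraries in the share of peaks at gene ends stay possible as an account of this distance. With that share as a covariate the camera adjusted p was 0.352. The distance of the list's median from that of all gene ends went from -0.44 to -0.08. The share is counted on the same peak lists as the ranks, so the covariate removes much of a general shift of gene ends. This fit therefore cannot decide whether the share accounts for the distance. The list's own median hardly moved (-0.12 and -0.16), while that of all gene ends fell from 0.32 to -0.08. The spread over members was 0.77 before and 0.45 after (SD), and the call ended because the distance shrank, while the median SE of the members stayed at 0.39 and 0.37. An effect of the genotype on these targets stays open, as does an effect of the genotype on the share itself.

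KO replicate 3 and KO replicate 1 had an interval at the upper end of Xist, the gene of the RNA that silences 1 X chromosome in females, and no WT library had one. The interval held rank 48210 in KO replicate 3 (chromosome X, 103483138 to 103483385) and rank 62924 in KO replicate 1 (103483116 to 103483357).

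KO replicate 3 also had no interval at the Y-linked genes Uty, Ddx3y and Eif2s3y, where the WT libraries had 12, 10 and 12 intervals, KO replicate 1 had 4 and KO replicate 2 had 7. A lower depth was argued against, since its background coverage of 6.88 was above the 6.37 of WT replicate 2 and the 5.89 of KO replicate 2, which had such intervals. It still had 10 intervals on chromosome Y in its whole list, against 35, 22 and 37 in WT and 17 and 18 in the other KO libraries. In the last 1 Mb covered it had 9, against 8, 5 and 11 in WT and 9 and 6 in KO replicates 1 and 2, so these do not set it apart. Elsewhere on the chromosome it had 1, at rank 126550, against 27, 17 and 26 in WT and 8 and 12 in KO replicates 1 and 2. A female animal may account for this, and its Xist interval at rank 48210 goes with that. It stays open, because it was not tested whether the intervals in the last 1 Mb come from chromosome Y or from reads shared with other chromosomes. KO replicate 1 had both kinds of interval, with Uty at rank 55814 against 7857 to 13037 in WT, and no explanation was tested for it. The labels used here give no sex, and sex stays untested as a source of other differences between these libraries.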
